A study of Homo sapiens with 4 samples.

How the data were processed

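RNA was sequenced from HaCaT keratinocytes carrying a control hairpin or a hairpin against lnc-DC, with 2 libraries per group that the labels call biological replicates. Nothing in the labels says whether the replicates were separate transductions, so p-values measure only the spread between these libraries. Per the labels' protocols, mRNA was purified from 5 µg of total RNA with oligo(dT) beads, fragmented, copied with dUTP in the second strand and sequenced as paired reads of 150 bases. Such a library captures polyadenylated RNA, so small nucleolar RNAs and ribosomal RNAs in the table stand for fragments that passed that selection.

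Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2 and edgeR were used, with no roles given. The genome build, annotation release, strand setting and treatment of reads that map to several places are not given in the sources used here. Of 58825 gene IDs, 58552 were found in GENCODE 29 (GRCh38), which was used for positions, transcript lengths, GC content and exon overlaps. The authors deposited FPKM values, fragments normalized to transcript length and library total, with 2 decimals. FPKM is relative to each library's total, so a change in a few abundant transcripts moves all other values, and overlapping or near-identical genes share reads in a way that the table does not show. The authors' deposited table also gives a fold (ratio) column, the knockdown mean FPKM over the control mean, and its log2. For 12381 of 12388 tested genes with both means above 0, the authors' deposited log2 values lay within 0.05 of the log2 ratio of the group means. There were 0 columns without a sample of the series.

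The table holds no counts, so the count-based test foreseen for that case was not used, and the test fixed in advance for normalized values took its place. Values were transformed as log2(FPKM + 1), and the 12411 genes with a mean of at least 1 FPKM in at least 1 group were tested with limma 3.58.1 in R 4.3.3 (trend on, robust off, group as the only term), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale are smaller than ratios of FPKM for low genes; folds given in the text are ratios of mean FPKM. With 2 libraries against 2 an exact permutation test cannot give a p below 0.333, so p-values rest on limma's pooling of spread across genes. A value of 0 may be a failed estimate, so such genes are described as listed at 0 and no fold is given against them.

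Depth was estimated from the table. For genes with 1 transcript, FPKM times length should step in whole reads, so the depth at which most low values came within 0.1 of a whole read was sought for each library. At these depths 28.4% to 31.9% of values were near whole, against a median of 17.0% to 17.8% over all depths tried, so whole reads were not recovered and only the relative depth is used. By this uncertain estimate both replicate 2 libraries were deeper than both replicate 1 libraries, with no imbalance between groups. Genes above 0 did not follow it in the control libraries (22780 in replicate 1, 22351 in replicate 2) and hardly differed in the knockdown libraries (22702 and 22722).

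Before the data were examined, 29 gene lists were fixed, of which 28 had a tested member. They were tested with camera from limma (correlation 0.01, two-sided, Benjamini-Hochberg over lists), with the estimated correlation and fry beside it. With an estimated correlation, camera rests on the 2 residual degrees of freedom of the fit. Few lists could pass there, so a call lost in that setting decides little about correlation among genes. The named genes followed a rule fixed at the same time: WFDC21P; up to 12 genes with the largest change in each direction among those past the threshold with a mean of at least 1 FPKM, a gene symbol and no overlap between groups; up to 4 members with the smallest p in each list described; and KRT5, KRT14, TP63, KRT1, KRT10, IVL, LOR, FLG, TGM1, SPRR1B, GRHL3, KLF4, ZNF750 and MKI67. Clone-based names were not taken as gene symbols. PTGFRN, MT-ND1, MT-ND2, MT-ND3, the mitochondrial rRNAs, SERPINB3, CLDN7, KRT7, HSPA1B, and the genes of the closing section were named after their values were seen. Gene Ontology terms were taken from the deposited table, and the 2713 with 10 to 300 tested genes were tested with camera; this was added after the data were seen.

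The fit was tested on simulated data, with values drawn independently for each of 12411 genes around its real mean. The spread was the replicate spread after limma's pooling across genes. In each of 5 draws 200 genes were changed, picked only among genes with a mean log2 value above 2. Among these the fit recovered 65.7% of genes changed 2-fold, 98.2% changed 4-fold and 100% changed 8-fold for the knockdown against control comparison. False calls made up 8.34% of calls, above the nominal rate, and 4.83% of unchanged genes had an unadjusted p under 0.05. Of 200 simulated lists with no change, 3% had a camera p under 0.05. As the simulated genes were independent, this does not test lists whose genes vary together. The recovery rates may be too high for the real data, because the simulated spread was already pooled. In the real fit MMP7, 4.76-fold lower, had a limma adjusted p of 0.0609, and KRT13, 3.65-fold lower, had 0.0533. ANKRD1, 4.19-fold higher, passed.

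Alternatives were median centring, quantile normalization, no filter beyond a value above 0, a mean of at least 5 FPKM, the replicate number as a block, each library left out in turn, limma without trend, a pseudocount of 0.1, a minimum log2 change of 1, the estimated correlation and fry. Added after the data were seen were nuclear genes alone rescaled to equal sums, removal of each library's trend on GC content and transcript length (splines with 4 degrees of freedom each), genes without exon overlap (HSPA1A and HSPA1B also left out), and an adjusted p under 0.1. Alternatives that need counts were not run. No library was left out of the main comparison.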

Results

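The data were 4 RNA-seq libraries from HaCaT cells, an established line of human keratinocytes that grows without a viral oncogene and can be driven to differentiate by calcium. The cells were kept in a medium with 1.2 mM calcium and carried either a control short hairpin RNA or a hairpin against the long noncoding RNA lnc-DC, both delivered by lentivirus, with 2 libraries per group. The stated aim was to describe how silencing lnc-DC alters the expression signature of keratinocytes induced to differentiate. The deposited table gave 1 FPKM value per gene and library for 58825 genes, of which 31201 were listed at 0 in all 4 libraries. Between 22351 and 22780 genes had a value above 0 in a library. Total read counts were not part of the table, but the spacing of low FPKM values gave a relative depth of 1.301 for control replicate 2, 0.994 for knockdown replicate 1 and 1.35 for knockdown replicate 2, with control replicate 1 set to 1. Across the 12411 tested genes, log2 values correlated at a Pearson r of 0.969 between the control libraries and 0.971 between the knockdown libraries, against 0.949 to 0.955 between groups; genes are not independent replicates. Mitochondrially encoded transcripts made up 41.2% and 41.9% of summed FPKM in the control libraries and 28.1% and 26.8% in the knockdown libraries.

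The targeted transcript was lower in both knockdown libraries. lnc-DC is the transcript of WFDC21P (ENSG00000261040), which GENCODE 29 places on the minus strand of chromosome 17 (GRCh38), from 60083566 to 60091885, as a transcribed unitary pseudogene. Its FPKM was 2.15 and 2.76 in the control libraries and 0.09 and 0.29 in the knockdown libraries, a 12.9-fold lower mean (8.47-fold without knockdown replicate 1 and 27.3-fold without knockdown replicate 2). On the log2(FPKM + 1) scale, which understates the change of a gene at this low level, it differed by -1.54 (SE 0.188). The groups did not overlap, yet the limma adjusted p of 0.0715 missed the threshold of 0.05, and it lay between 0.0548 and 0.254 under the 13 alternative settings. The authors' deposited table lists a log2 ratio of -3.68 for this gene.

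**Figure D1:**
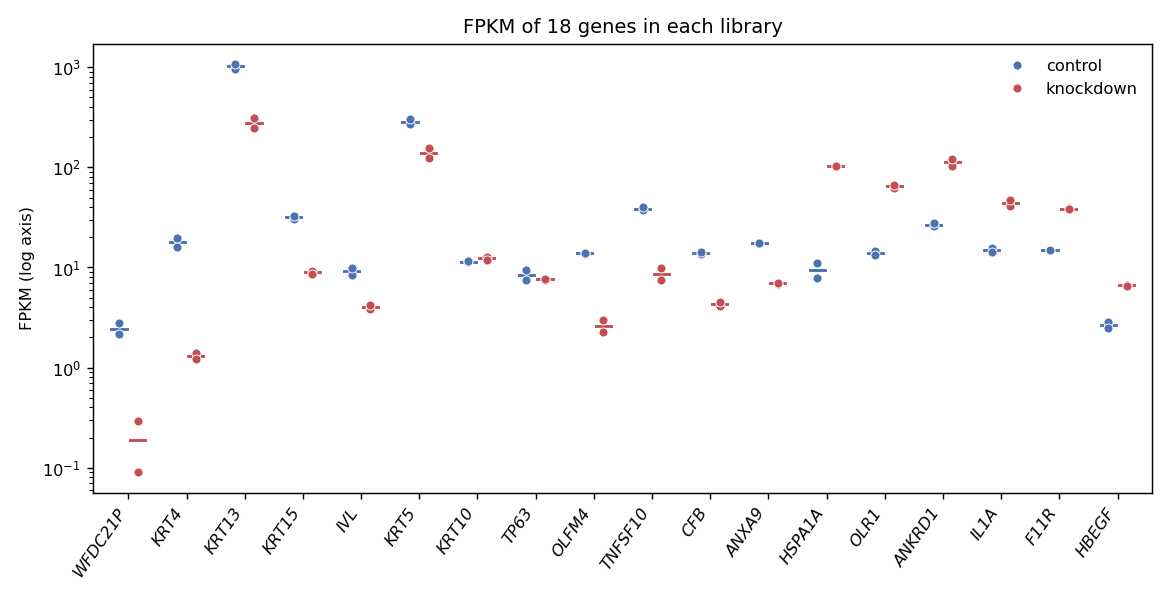
FPKM on a log axis for 18 genes, with 1 point per library and a short line at the mean of each group of 2 (control in blue, knockdown in red). WFDC21P, KRT4, KRT13, KRT15 and IVL lie lower in both knockdown libraries, HSPA1A, OLR1, ANKRD1 and IL1A lie higher, and TP63 and KRT10 lie close together.

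The genes that fell in the knockdown included KRT4 and KRT15, the only keratins past the threshold over all genes. KRT4, a keratin of wet stratified epithelia, fell 13.6-fold, from 17.9 ± 2.35 to 1.31 ± 0.134 FPKM (mean ± SD, n = 2 per group; limma adjusted p = 0.0261). KRT15, a keratin of basal cells, fell 3.53-fold to 8.97 ± 0.375 FPKM (adjusted p = 0.0362). LYPD2 fell 33.0-fold from 6.11 ± 0.368 FPKM, and OLFM4, a secreted glycoprotein of epithelial progenitors, fell 5.29-fold from 13.8 ± 0.106 FPKM. TNFSF10, the death ligand TRAIL, fell from 38.6 ± 2.03 to 8.71 ± 1.73 FPKM, and CFB, complement factor B, fell from 14.0 ± 0.615 to 4.32 ± 0.311 FPKM, with limma adjusted p between 0.0261 and 0.0438 for these 4 genes. Other genes that fell were ZSWIM9 (18.1-fold, or 32.3-fold without knockdown replicate 1), ATP6V1B1, a subunit of the vacuolar proton pump (9.49-fold), OPN3 (3.19-fold), BANF1, a DNA-binding protein of the nuclear envelope (2.86-fold), PTGFRN (2.67-fold) and ANXA9 (2.51-fold), with adjusted p between 0.0366 and 0.0495. The largest fitted falls also included the small nucleolar RNA SNORD5 (46.0-fold, adjusted p = 0.0362) and the ribosomal protein pseudogene RPL32P29 (15.7-fold, adjusted p = 0.0277).

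Genes that rose included the inducible chaperone HSPA1A, from 9.49 ± 2.23 to 104 ± 0.636 FPKM (n = 2 per group, limma adjusted p = 0.0261). Its near-identical copy HSPA1B stood at 94.7 ± 3.51 and 102 ± 0.608 FPKM, so the split of reads between them is uncertain. OLR1, a receptor for oxidised LDL, rose from 14.0 ± 0.792 to 64.5 ± 2.18 FPKM (adjusted p = 0.0261). ANKRD1, a known target of YAP, rose 4.19-fold to 112 ± 11.6 FPKM (adjusted p = 0.0362). The alarmin IL1A rose 2.95-fold to 44.3 ± 4.19 FPKM (adjusted p = 0.0463), and F11R, the junctional adhesion molecule JAM-A, rose 2.58-fold to 38.6 ± 0.587 FPKM (adjusted p = 0.0418). PIK3R2, a regulatory subunit of PI3 kinase, was listed at 0.63 and 0.43 FPKM in the control libraries and at 16.6 and 12.8 in the knockdown libraries (adjusted p = 0.0261). ARMCX5 (7.21-fold), CGGBP1 (4.23-fold), FYTTD1, an mRNA export adaptor (3.78-fold), DCTN4 (3.36-fold), MZT1 (3.04-fold) and the small nucleolar RNAs SNORA58B (8.60-fold) and SNORA14B (8.92-fold) also rose, with adjusted p between 0.0362 and 0.0495.

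In total, limma called 14 genes higher and 17 lower in the knockdown among 12411 tested, at an adjusted p under 0.05, and each of the 31 changed by at least 1 on the log2 scale; 4 of them bear only a clone-based name. Unadjusted p was under 0.05 for 2827 genes, of which 1834 were higher and 993 lower, where chance alone would give 621. The median log2 fold change of all tested genes was 0.0909, so counts above 0 in lists are not to be read against an even split. The values of the groups did not overlap for 54.8% of tested genes, where chance gives 33.3%. Under quantile normalization the same test called 17 genes higher and 40 lower. Of the 31 genes, 14 share exons on the same strand with another gene of GENCODE 29, among them PIK3R2, SNORD5, SNORA58B, RPL32P29, ARMCX5, ATP6V1B1, KRT15, CFB, OPN3 and F11R, so their values depend on how reads were divided. The 3 named small nucleolar RNAs are 73 to 136 bases long, shorter than the read length of 150 bases. No gene passed when any 1 of the 4 libraries was left out (1781 to 2235 genes with unadjusted p under 0.05) or when genes of low value were kept (3876 genes).

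**Figure D2:**
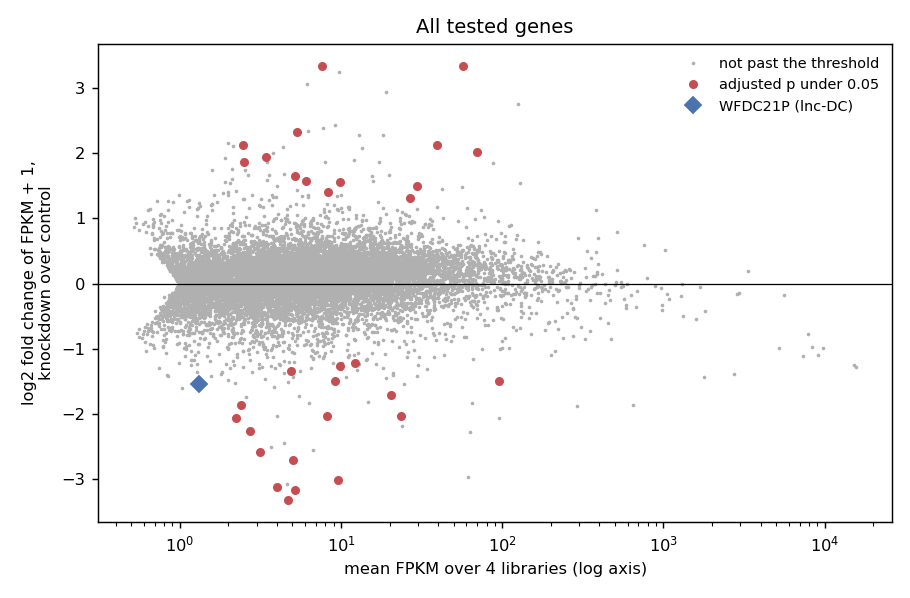
Log2 fold change of FPKM + 1 (knockdown over control) against the mean FPKM over 4 libraries, on a log axis, for the 12411 tested genes. The 31 genes past an adjusted p of 0.05 are red, 14 above and 17 below 0, and WFDC21P is the blue diamond at -1.54; in grey are the genes that did not pass.

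The list of spinous and early differentiation genes was lower as a set in the knockdown. Only 10 of its 20 genes were measured, so the result covers only part of the list. Of the 10 measured members 7 lay below 0 on the log2 scale, and the median log2 fold change was -0.76. Over all genes 1 fell and 9 did not pass, while 5 fell and none rose when adjusted over the list alone. Besides KRT4, these were KRT13, the keratin partner of KRT4 (1020 ± 71.3 to 280 ± 46.8 FPKM, n = 2 per group), IVL, the cornified envelope precursor involucrin (9.23 ± 1.07 to 4.04 ± 0.276 FPKM), LY6D (2.19 ± 0.304 to 0.360 ± 0.0707 FPKM) and SERPINB3, all with the knockdown values below the control values. The set test of limma, camera, gave an adjusted p = 3.89e-05, which became an adjusted p = 0.334 with an estimated correlation between genes. The fry test, which asks only whether the genes move one way, gave an adjusted p = 0.0345. KRT10, the other spinous keratin always reported here, had 11.4 ± 0.247 FPKM in control and 12.3 ± 0.643 FPKM in knockdown cells (adjusted p = 0.601), a difference whose sign turned under quantile normalization. Among the 10 genes not measured, KRT1, KRT2, DSG1, DSC1, KRTDAP and LGALS7 were listed at 0 in all 4 libraries. TGM1, also not measured, did not exceed 0.5 FPKM.

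Genes of the later layers had low values in these libraries, and a value at or near 0 does not tell absent RNA from reads that were not assigned. Only 8 of 37 genes of the granular and cornified envelope list reached the filter, and none of 18 late cornified envelope genes did, where the highest value was 0.22 FPKM. LOR, which codes for loricrin, was listed at 0 in all 4 libraries. FLG did not exceed 0.64 FPKM, and SPRR1B was listed at 0 in 3 libraries and at 0.15 in the fourth. Of the 8 measured members, 1 fell over all genes (ANXA9) and 7 did not pass; adjusted over the list alone, 3 fell and 1 rose. The members that fell were ANXA9, SCEL and PPL (periplakin), and the one that rose was EVPL (envoplakin), from 1.84 ± 0.0707 to 5.58 ± 0.742 FPKM (n = 2 per group). The camera adjusted p for the list was 0.0527, short of the threshold, with a median log2 fold change of -0.25; it became 0.00566 with a stricter filter and 0.0488 with a smaller pseudocount, within a range up to 0.495 over all settings.

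Basal keratinocyte genes were lower as a set, with 13 of 19 measured members below 0 on the log2 scale and a median of -0.12. KRT15 fell over all genes and 18 members did not pass; adjusted over the list alone, KRT15, KRT5 and the cadherin CDH3 fell and none rose. KRT5, the main basal keratin, had 287 ± 24.3 FPKM in control and 140 ± 22.9 FPKM in knockdown cells (n = 2 per group, limma adjusted p = 0.0833). The integrin subunit ITGA2 stood at 16.7 ± 4.04 and 32.6 ± 6.75 FPKM. TP63, the master regulator of stratified epithelium, had 8.44 ± 1.29 and 7.63 ± 0.113 FPKM (adjusted p = 0.626), and KRT14, the usual partner of KRT5, did not exceed 0.35 FPKM in any library, which is unusual for a line labelled HaCaT. Camera gave an adjusted p = 0.0125 for the list, an adjusted p = 0.66 with an estimated correlation, 0.282 with fry and 0.14 without control replicate 1.

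Regulators of differentiation followed with a smaller shift, a median of -0.11 over 20 measured members (camera adjusted p = 0.0289; adjusted p = 0.663 with an estimated correlation). None passed over all genes, and 2 fell and none rose when adjusted over the list alone. These were ELF3, an epithelial ETS factor, with 52.2 ± 1.58 FPKM in control and 23.3 ± 0.870 FPKM in knockdown cells (n = 2 per group), and the long noncoding RNA TINCR, with 3.71 ± 0.346 and 1.85 ± 0.00707 FPKM. KLF4 stood at 5.44 ± 0.255 and 3.71 ± 0.0919 FPKM (limma adjusted p = 0.126), and GRHL3 at 1.96 ± 0.332 and 2.42 ± 0.134 FPKM (adjusted p = 0.439). FOSL1 stood at 14.2 ± 7.11 and 30.7 ± 7.33 FPKM. ZNF750 was below the filter, at 0.23 and 0.18 FPKM in the control libraries and 0.02 and 0 in the knockdown libraries. The call was lost with fry (0.288), the stricter filter (0.0862), GC and length removed (0.0746), overlapping genes left out (0.0705), without control replicate 1 (0.14) and without knockdown replicate 2 (0.292).

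**Figure D3:**
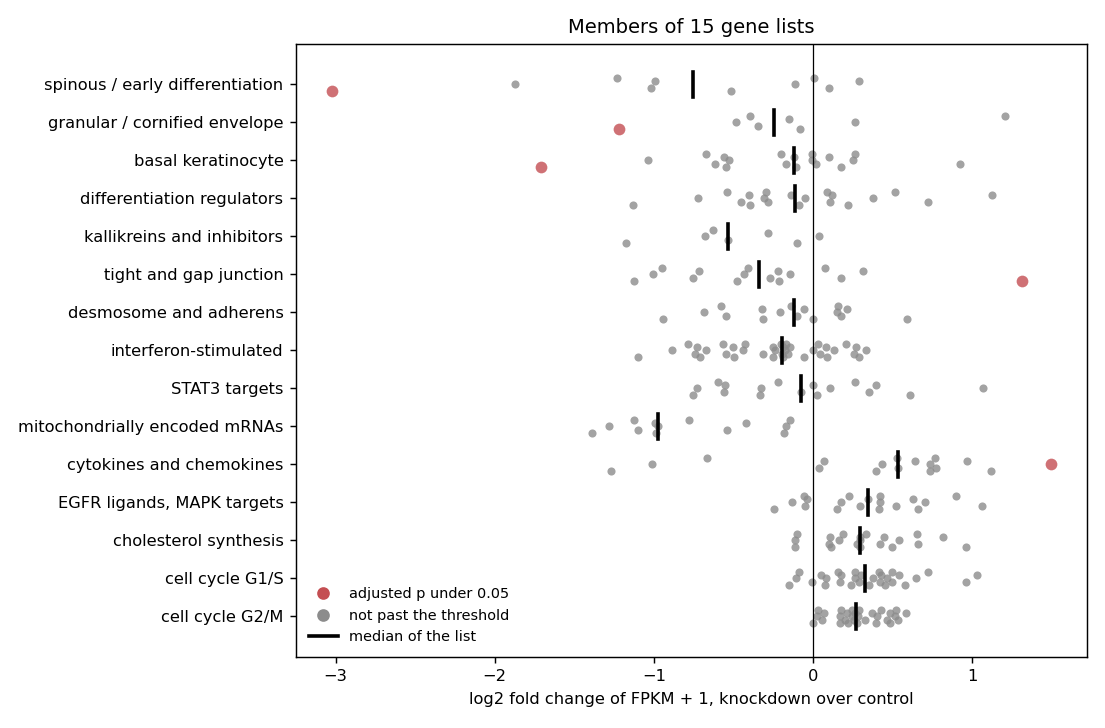
Log2 fold change of FPKM + 1 (knockdown over control) for each measured member of 15 gene lists, with a black bar at the list median and red points for members past an adjusted p of 0.05 over all genes. The median is -0.76 for the spinous list and 0.53 for cytokines and chemokines. All 30 G2/M members lie above 0 (25 under median centring or quantile normalization). The mitochondrially encoded list lies below 0 here but not under quantile normalization, which equalizes the highest values between libraries.

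Genes of epidermal proteolysis and cell contacts were also lower as sets. Among 7 measured kallikreins and their inhibitors none passed over all genes, and 4 fell and none rose when adjusted over the list alone: the desquamation proteases KLK7 (4.15 ± 0.325 to 1.28 ± 0.134 FPKM, n = 2 per group) and KLK5 (21.0 ± 0.856 to 14.2 ± 0.346 FPKM), with KLK6 and KLK8. Of 16 tight and gap junction genes, F11R rose over all genes and the rest did not pass; adjusted over the list alone 4 fell, namely CGN (cingulin), CLDN1 (151 ± 2.26 to 91.5 ± 2.19 FPKM), TJP3 and CLDN7, and 1 rose. Of 16 desmosome and adherens junction genes none passed over all genes and 4 fell when adjusted over the list alone, among them CDH1, which codes for E-cadherin (41.3 ± 0.396 to 27.3 ± 1.85 FPKM), and NECTIN4. Camera gave adjusted p = 0.000278, 0.00279 and 0.0289 for these lists; with an estimated correlation these became an adjusted p = 0.334, 0.334 and 0.657, and with fry 0.0345, 0.0569 and 0.112. The desmosome and adherens junction call was also lost without control replicate 1 (0.106), without knockdown replicate 1 (0.104) and with no filter (0.0671), within a range of 0.0137 to 0.657.

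Interferon-stimulated genes were lower as a set while cytokine genes were higher. Of 37 measured interferon-stimulated genes 27 lay below 0; none passed over all genes, and 7 fell and none rose when adjusted over the list alone. OASL went from 27.3 ± 1.70 to 14.3 ± 0.0919 FPKM (n = 2 per group), IRF1 from 21.3 ± 0.453 to 12.3 ± 1.03 FPKM, and DDX60 and ISG15 were also among the 7. Of 17 measured cytokines and chemokines IL1A rose over all genes and 16 did not pass; adjusted over the list alone 10 rose and 3 fell. IL1B, at 16.49 and 16.75 FPKM in the control libraries and 27.84 and 30.18 in the knockdown libraries, was among those that rose, whereas the chemokines CCL5 (6.66 ± 0.297 and 2.79 ± 0.0495 FPKM) and CCL22 (5.62 ± 0.509 and 1.76 ± 0.368 FPKM) were among those that fell. Camera gave adjusted p = 2.18e-05 for the interferon list and 0.0237 for the cytokine list, and an adjusted p = 0.334 for each with an estimated correlation; fry gave 0.0611 and 0.0345. The cytokine call was lost without control replicate 1 (0.0842), within a range of 0.000287 to 0.334 over all settings.

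Targets of STAT3 gave a median of -0.08 over 17 measured members (camera adjusted p = 0.0376; adjusted p = 0.638 with an estimated correlation). None passed over all genes; adjusted over the list alone 5 fell, among them LRG1, the kinase PIM1 and JUNB, and 1 rose, the receptor subunit IL6ST. The call was lost in 8 of 16 alternative settings, among them fry (0.288), without control replicate 1 (0.2), knockdown replicate 1 (0.0517) and knockdown replicate 2 (0.0797), within a range of 0.0269 to 0.638. EGFR ligands and MAPK targets were higher, with a median of 0.34 over 19 members (adjusted p = 0.0289; adjusted p = 0.66 with an estimated correlation), and the ligands HBEGF (2.67 ± 0.262 to 6.63 ± 0.0919 FPKM, n = 2 per group) and AREG (1.97 ± 0.00707 to 4.53 ± 0.410 FPKM) rose when adjusted over the list alone, none fell, and none passed over all genes. That call was lost with fry (0.112), without control replicate 1 (0.0799), without knockdown replicate 1 (0.0886), with the stricter filter (0.62) and without overlapping genes (0.0521), within a range of 0.00126 to 0.66.

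Genes of proliferation and sterol synthesis were higher as sets. Of 30 genes of G1/S and S phase 26 lay above 0 with a median of 0.32. Under median centring 23 lay above 0, and under quantile normalization 24. None passed over all genes, and 6 rose and none fell when adjusted over the list alone. MCM6, a helicase subunit of DNA replication, went from 24.7 ± 0.898 to 49.0 ± 3.20 FPKM (n = 2 per group), and CDC25A, CCNE2 and MCM10 rose with it. All 30 genes of G2 and M phase lay above 0 with a median of 0.27, but 25 of 30 did under median centring or quantile normalization and 27 with nuclear genes rescaled, and none passed over all genes or when adjusted over the list alone. MKI67, the proliferation marker Ki-67, had 62.0 ± 15.2 and 68.7 ± 4.17 FPKM (limma adjusted p = 0.636). Of 21 cholesterol synthesis genes 18 lay above 0; none passed over all genes, and SQLE rose when adjusted over the list alone (12.4 ± 0.0990 to 20.3 ± 0.912 FPKM). Camera gave adjusted p = 0.000428, 0.000837 and 0.0109 for these lists, and with an estimated correlation an adjusted p = 0.334, 0.5 and 0.334; fry gave 0.0345, 0.064 and 0.0345. Across genes, log2 fold changes correlated with GC content (Spearman rho -0.228), and genes are not independent replicates.

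All 13 mitochondrially encoded mRNAs lay below 0, with a median of -0.98, except that under quantile normalization 6 lay above 0, 6 below and 1 at 0. None passed over all genes, and 9 fell when adjusted over the list alone. MT-CO2, a subunit of cytochrome c oxidase, went from 22310 ± 2843 to 9123 ± 28.8 FPKM (n = 2 per group) and MT-ATP6 from 3987 ± 420 to 1521 ± 88.7 FPKM, and MT-ATP8 and MT-CYB were also among the 9. MT-ND1 stood at 3089 ± 18.3 and 2798 ± 336 FPKM and MT-ND2 at 5979 ± 565 and 5261 ± 430 FPKM. Of the ribosomal RNAs, MT-RNR2 stood at 2.37-fold less in the knockdown (limma adjusted p = 0.102), while MT-RNR1 had 3121 ± 162 and 3594 ± 722 FPKM. Camera gave an adjusted p = 6.74e-10, an adjusted p = 0.334 with an estimated correlation, and 0.722 under quantile normalization. Quantile normalization gives every library the same sorted values, and these mRNAs were among the highest. It therefore largely removes a fall that they share and cannot decide on one. In the other settings that tested these mRNAs all 13 lay below 0. Of those settings only median centring and the GC and length correction could turn a sign, as the groups did not overlap.

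**Figure D4:**
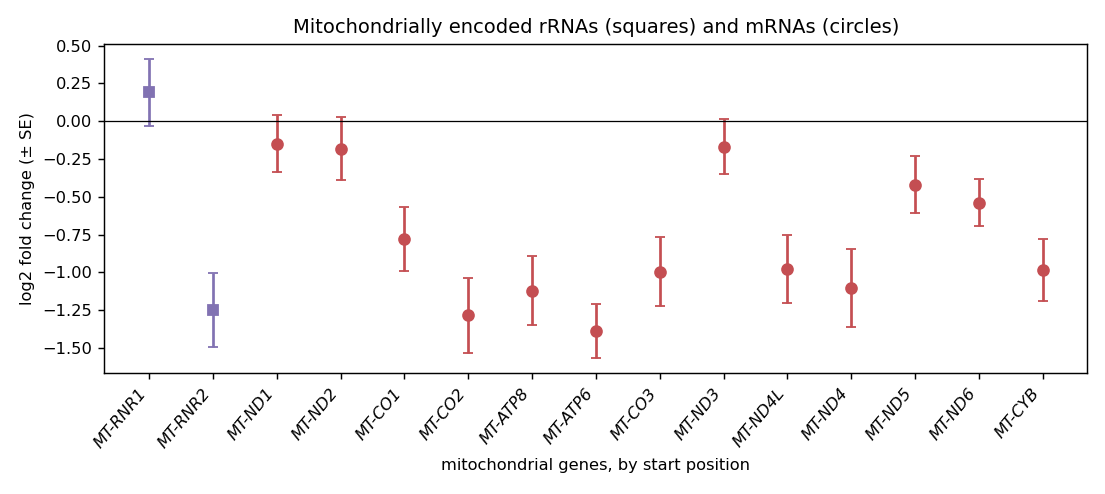
Log2 fold change of FPKM + 1 (knockdown over control, ± SE) for mitochondrially encoded rRNAs (squares) and mRNAs (circles), in the order of their start positions. MT-ATP6 lies lowest at -1.39, while MT-ND1, MT-ND2 and MT-ND3 lie between -0.18 and -0.15. Under quantile normalization, which equalizes the highest values between libraries, 6 of the 13 mRNAs lie above 0.

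Markers of other cell types were scarce. Of fibroblast markers only FBLN1 was measured (5.37 ± 0.382 and 2.60 ± 0.205 FPKM, n = 2 per group; camera adjusted p = 0.0373 for this single gene, and an adjusted p = 0.407 with an estimated correlation). The call held in only 5 of 15 alternative settings, and was lost when any 1 library was left out (0.0537 to 0.0781), under median centring (0.0608), under quantile normalization (0.0652), with no filter (0.186) and with GC and length removed (0.0746). Of melanocyte markers only MITF (3.46 ± 0.771 and 3.90 ± 0.219 FPKM) and of endothelial markers only CDH5 (4.51 and 3.52 FPKM in the control, 3.88 and 6.42 FPKM in the knockdown libraries) were measured, and of leukocyte and dendritic cell markers CD14, HLA-DRA and CD74, none above 5.38 FPKM. The simple epithelium markers were abundant in both groups and lower as a set, with 5 of 5 below 0 except that KRT7 turned under quantile normalization, with GC and length removed and without knockdown replicate 2 (camera adjusted p = 0.011; adjusted p = 0.334 with an estimated correlation, 0.0592 under quantile normalization and 0.0582 with GC and length removed, within a range of 0.00768 to 0.334). KRT19 stood at 353 ± 25.8 and 200.3 ± 2.81 FPKM and fell when adjusted over the list alone, and KRT18 stood at 275 ± 22.1 and 231 ± 6.93 FPKM. Of 28 lists with a measured gene, 12 missed the threshold, with camera adjusted p from 0.0527 to 0.762 in the main setting. Besides the granular list and the marker lists of melanocytes, leukocytes and endothelium, these were epidermal lipids, antimicrobial and psoriasis genes, p53 targets, mesenchymal matrix, Notch, hypoxia and glycolysis, the unfolded protein response and the chromosomal neighbours of WFDC21P. Among these, the antimicrobial list passed as lower with the stricter filter (0.0111), without control replicate 1 (0.0405) and without knockdown replicate 2 (0.0183), and Notch as lower with the stricter filter (0.0104). Hypoxia and glycolysis passed as higher with no filter (0.0481), and the unfolded protein response as higher without control replicate 2 (0.0279); over all settings these 4 lists reached up to 0.778, 0.68, 0.925 and 0.961.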

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

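The nuclear-only rescaling, the GC and length correction, the restriction to genes without exon overlap and the looser threshold of 0.1 were chosen after the data were seen; the other settings were not. Alternatives that need counts were not run, and lnc-DC has no value with the stricter filter, which removes it. The log2 change of lnc-DC stayed negative and short of the threshold in all 13 settings, from -1.66 to -1.41 when 1 library was left out and at -3.22 with a pseudocount of 0.1.

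The 14 higher and 17 lower genes became 0 and 0 with no filter, where more genes were tested (3876 with unadjusted p under 0.05), and 0 to 0 for both directions when 1 library was left out, which leaves fewer samples (unadjusted: 2235 and 1979 without control replicates 1 and 2, 1783 and 1781 without knockdown replicates 1 and 2; the lone sample is assumed to vary like the other group). Higher calls became 32 with the stricter filter, 8 without trend, 3 without overlapping genes and 261 at the looser threshold. Lower calls became 40 with quantile normalization, 9 without trend, 31 with GC and length removed, 4 without overlapping genes and 245 at the looser threshold. The cause was not tested. Of the 31 called genes all that were tested had the same sign in each setting (21 with the stricter filter, 16 without overlapping genes and HSPA1A, 31 elsewhere). Filters, the block, the fit without trend and the fit without overlapping genes keep each log2 change, so no sign could turn there. Nor could one turn when 1 library was left out or with the smaller pseudocount, as these genes did not overlap between groups. Only median centring, quantile normalization, nuclear rescaling and the GC and length correction could turn a sign. Of the 31 genes, 25 remained called under median centring, 30 under quantile normalization and 27 with the smaller pseudocount.

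The labels give the replicates only a shared number, and by the uncertain depth estimate both replicate 2 libraries were the deeper ones. With the replicate number as a block, limma called 0 higher and 0 lower genes at an adjusted p under 0.05, with 3791 at an unadjusted p under 0.05; differences between replicates 1 and 2 correlated across genes at a Pearson r of 0.124 and a Spearman rho of 0.351 between the groups.

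Among the main lists, adjusted p ranged over all settings from 6.11e-06 to 0.334 (spinous), 0.00566 to 0.495 (granular), 0.00219 to 0.66 (basal) and 0.00998 to 0.663 (regulators), all lower. With an estimated correlation it was 0.334 for the spinous list, 0.66 for basal and 0.663 for regulators, and with fry 0.282 for basal and 0.288 for regulators. Regulators gave 0.0862 with the stricter filter, 0.0746 with GC and length removed and 0.0705 without overlapping genes; the granular list gave 0.00566 with the stricter filter and 0.0488 with the smaller pseudocount. With 1 library left out the range was 0.00219 to 0.14 for basal, 0.00998 to 0.292 for regulators, 0.0744 to 0.164 for granular and 6.11e-06 to 0.00083 for spinous. Of the other lists 13 passed, 0 with an estimated correlation and 7 with fry. The cause was not tested.

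Signs turned for genes and lists that had not passed over all genes or lists. Under quantile normalization these were KRT10 (-0.0179), KRT7 (0.0707), CD74 (-0.0491), MT-RNR2 (0.0396), MT-ND1 (0.188), MT-ND2 (0.57) and MT-ND3 (0.188). CD74 also turned under median centring (-0.0642) and nuclear rescaling (-0.0155), and KRT7 (0.0242) and MITF (-0.0091) with GC and length removed. With 1 library left out, log2 changes ranged from -0.262 to 0.0184 for TP63, -0.0816 to 0.416 for MKI67, -0.0323 to 0.572 for CDH5, -0.127 to 0.168 for CD74, -0.0342 to 0.32 for MITF, -0.171 to 0.0651 for KRT7, -0.0162 to 0.396 for MT-RNR1, -2.62 to 1.8 for CLDN4 (1.37 without knockdown replicate 1) and -0.878 to 3.01 for MYC. Lists turned with no filter for epidermal lipids (0.471), endothelial markers (0.801) and melanocyte markers (0.757), with the stricter filter for mesenchymal matrix (0.836), with GC and length removed for chromosomal neighbours (0.931), leukocyte markers (0.937) and melanocyte markers (0.937), and with fry for leukocyte markers (0.959) and p53 targets (0.718). With 1 library left out they turned for epidermal lipids (0.98 without control replicate 2, range 0.226 to 0.996), melanocyte markers (0.834 without control replicate 2, range 0.532 to 0.977) and endothelial markers (0.787 without knockdown replicate 2, range 0.249 to 0.923); values for lists are adjusted p. The cause was not tested. Of 443 comparisons of a list with its alternative, 367 kept direction and side of the threshold. These include 28 from limma without trend, an option that camera does not use, so they could not differ. That setting is also among the alternatives counted for each list above. Low values limit precision, as FPKM has 2 decimals and depth is known only in relative terms.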

Other observations

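The Gene Ontology terms, the genes picked from them and most tests below were chosen after the results for genes and lists were seen. The tests after the GC and length correction were set out before their result. The estimated correlation and quantile normalization of the gene lists were planned settings.

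Genes of ribosome and mRNA production were higher in the knockdown as sets, alongside lower keratinization terms. Of 2713 terms tested with camera, 57 were higher and 18 lower at an adjusted p under 0.05. None passed with an estimated correlation, but with 2 residual degrees of freedom that setting has little power to pass any. Ribosome biogenesis ranked first (97 genes, 89 above 0, median log2 fold change 0.33, camera adjusted p = 5.22e-06), and 24 of its genes rose when adjusted over the term alone. Over all tested genes the median was 0.0909, which lifts counts above 0 in every term. NOL11, a factor of pre-rRNA transcription, had 15.5 ± 0.297 FPKM in control and 31.1 ± 1.73 FPKM in knockdown cells (n = 2 per group), and the ribosome assembly factor RIOK1 had 10.5 ± 0.269 and 19.9 ± 1.27 FPKM. mRNA splicing via the spliceosome (225 genes, 195 above 0, adjusted p = 0.000128) and mRNA export from the nucleus (96 genes, 83 above 0, adjusted p = 0.00199) were higher too, although 0 and 2 of their genes rose when adjusted over the term alone. Keratinization (33 genes, 27 below 0, camera adjusted p = 1.93e-05) was lower. Its genes with the smallest p included KRT4, KRT15, KRT13, IVL, KRT19 and KRT5, reported above in other lists, and EVPL, which rose. The term is thus not independent of those lists. Serine-type endopeptidase activity (50 genes, 29 below 0, camera adjusted p = 0.00455) was also lower. Its genes with the smallest p included CFB, KLK7 and KLK6, reported above, so it is not independent of those results either. In this term 11 genes fell when adjusted over the term alone, among them PLAT, tissue plasminogen activator (35.4 ± 1.17 to 16.5 ± 0.594 FPKM), and the metalloprotease MMP7 (10.4 ± 1.81 to 2.19 ± 0.559 FPKM).

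Several keratin values differ from those usual for HaCaT cells, in which KRT14 and KRT17 are abundant; the identity of the cells rests on the label, and whether reads of these genes went unassigned was not tested. KRT7 stood at 256 ± 0.686 FPKM in control cells, KRT8 at 135 ± 4.04 and KRT13 at 1020 ± 71.3 (n = 2), while KRT14 did not exceed 0.35, KRT16 0.35 and KRT17 0.85 FPKM in any library, and VIM stood at 0.145 ± 0.0919 FPKM in control cells. Some genes differed more within a group than between groups. CLDN4 had 0.87 and 39.3 FPKM in the control libraries and 0.90 and 21.5 in the knockdown libraries, and MYC had 34.3 and 1.38, and 11.6 and 28.3.

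Chance was checked by splitting the 4 libraries 2 against 2 in each of the 3 possible ways. The real split called 31 genes and the highest of the other splits 3; only 1 of the 3 splits gave as many, and 3 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 2827 genes and the highest other split 474.

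A first pattern is the large changes of genes that overlap another gene. Such genes made up 45.2% of the 31 called genes and 17.2% of the other tested genes (odds ratio 3.96, Fisher's exact test, two-sided, p = 0.000284), so reads assigned differently between overlapping gene models may account for some calls. In 4 called genes the overlapping genes moved the opposite way by at least 0.5 of the gene's own FPKM change. One of these is PIK3R2 (chromosome 19, 18153118 to 18170540), which went from 0.530 ± 0.141 to 14.7 ± 2.71 FPKM (n = 2 per group) while AC007192, a model that runs from 18153158 through IFI30 to 18178117, went from 7.96 ± 0.134 to 0.0200 ± 0.0141. Against this as the whole cause, 17 called genes share no exon on the same strand with another gene of GENCODE 29, including KRT4, OLFM4, TNFSF10, OLR1, ANKRD1 and IL1A. The fit without overlapping genes, which also leaves out HSPA1A and HSPA1B, tested 16 of the 17. The 16 have the same log2 changes there as in the main fit, so their signs could not turn. Only 7 stayed past the threshold. A split with HSPA1B alone would leave the sum of HSPA1A and HSPA1B level. Yet the sum differed by 0.98 on the log2 scale, from 104.2 ± 5.74 to 206.4 ± 1.25 FPKM (n = 2 per group). A change in transcription after the knockdown stays open for these genes.

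A further pattern is the uneven change of mitochondrially encoded mRNAs. Under quantile normalization 6 lay below 0 and 6 above, but that setting equalizes the highest values between libraries and cannot show a shared fall. The spread of these mRNAs was tested only without it. One scaling factor per library would move all 13 alike, but their log2 changes had an SD of 0.436, 3.40 times the 0.128 expected from replicate differences. Reads moved to nuclear copies would raise those copies, but the summed FPKM of 7 copies changed by -1.34 on the log2 scale. The sum stood at 4051.55 and 3507.88 in the control libraries. In the knockdown libraries, which differed from each other, it stood at 2115.83 and 1045.34. Differences in poly(A) capture of mitochondrial RNA between the groups, and an effect of the knockdown, were not tested and stay open.

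Another pattern is the opposite shift of spinous and interferon-stimulated genes against G1/S genes, since genes lower at an unadjusted p under 0.05 had a median GC content of 53.2% and those higher 45.0%. After each library's trend on GC content and transcript length was removed (99.9% of genes had both), camera gave an adjusted p = 0.000537 for the spinous list, 0.000403 for G1/S and 1.94e-05 for the interferon list. Their median log2 fold changes went from -0.76 to -0.84, from 0.32 to 0.27 and from -0.19 to -0.29. The correction also removed each library's mean offset, and the median over all tested genes went from 0.0909 to 0.0214. These moves of the list medians are thus not a measure of the GC trend. Over all settings adjusted p ran up to 0.334 for each, the value with an estimated correlation. The median GC content was 52.8% in the spinous list, 47.2% in the interferon list and 49.9% in the G1/S list. The lower interferon list was thus less GC-rich than the higher G1/S list, against the GC trend. For the interferon list the correction was therefore no real test of GC content. The G1/S median lay between the 45.0% of higher genes and the 53.2% of lower genes, so the correction could decide little there. The spinous list, at 52.8%, stayed lower after the correction, so the GC and length trend alone does not account for its shift. An effect of the knockdown, of differing growth of the cultures or of correlation among the genes stays open.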
